A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

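Ribosome footprints of 8 yeast libraries in 4 groups of 2 were compared within 2 datasets, purified tagged ribosomes (GA/AG against WT) and total lysates (cisplatin against DMSO). The deposited gene tables hold a count of reads per gene, and the deposited position tables hold reads at each transcript position with the library size and their RPM, per the file headers. Per the submitters' processing notes, cutadapt 2.6, Bowtie2 2.3.5, STAR 2.7.1a and genome build sacCer3 were used to make them. In every position table RPM, as the authors deposited it, was checked to be reads scaled by the library size given in the table, so whole reads were used. How reads shared between genes were treated, and the strand used for the gene tables, is not stated, so near-identical and overlapping genes are uncertain. The 2 kinds of table differ: 361 genes of the purified dataset and 38 of the other had over 10 times more gene reads than reads placed in their coding sequence. The reverse is seen in the DMSO and cisplatin libraries, where DMSO replicate 1 has 5968 gene reads of TEF1 against 148338 placed, 96267 against 176463 of TDH3 and 64712 against 113390 of ENO2.

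Gene reads per library ran from 1737727 (cisplatin replicate 1) to 10566159 (WT replicate 2), and position reads from 1752775 (cisplatin replicate 1) to 8467366 (DMSO replicate 2). Variation between replicates exceeded counting error, with chi-square per degree of freedom of 9.02 (WT), 12.7 (GA/AG), 2.80 (DMSO) and 17.0 (cisplatin), so errors come from replicates and counting error was not needed. Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr with its defaults) within each dataset, at a Benjamini-Hochberg adjusted p below 0.05. The biological coefficient of variation was 0.120 for GA/AG against WT and 0.0914 for cisplatin against DMSO. Gene changes are log2 fold changes ± SE, and list medians are on the same scale. Of 6692 gene identifiers, 6008 matched a locus tag that gave a symbol.

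Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. Of 26 lists fixed before the data were examined, 25 were tested, and the retrotransposon list matched no gene in the files. Tests, lists, the first set of alternatives and the rule for naming genes were also fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM and the same direction in all 4 pairs of libraries, the 2 members of each list with the lowest p, and GCN4, HEL2, RPL3 and GAL7. One member that the rule took from a list is not reported here. For codons it took the 4 largest rises and falls at each site, and for codon positions the 4 largest rises and falls past the threshold.

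Of 6468 transcripts in the position tables, 6410 were kept, without 20 mitochondrial ones, 36 lacking an ATG at the annotated start and 2 with a missing or internal stop codon. They held 96.0% to 98.8% of position reads. Reads lay 3 nt after the A of the start codon at the start peak, so each position was taken as the first nucleotide of the A-site codon. For codon occupancy, polarity and single codon positions the coding body ran from codon 16 to 10 codons before the stop. For windows it ran from codon 51 to the same end. Codon occupancy was averaged over 2232 genes (GA/AG) and 1935 genes (cisplatin) with at least 100 body reads in every library and at least 30 body codons, each divided by its gene mean, and tested with limma on the log2 scale. Windows, placed by the P site 3 nt before the A site, were the 5' UTR (50 to 4 nt upstream of the start), the start codon, codons 3 to 50, the stop codon and the 3' UTR (7 to 60 nt downstream). The start codon window holds codons 1 and 2, and the stop codon window holds the last sense codon and the stop codon. Each was tested with edgeR using body reads as offset. Genes needed at least 100 body reads in every library and at least 20 window reads over the 4 libraries. Single codon positions with at least 20 reads were tested in the same way, with the body from codon 16 as offset. Polarity, from -1 at the 5' end to 1 at the 3' end, was tested with limma, and frame shares with an exact permutation test. Of 5881 kept transcripts with a protein-coding locus tag, 229 have another reading frame of the same strand within 100 nt. They were left out of all windows, because their UTR windows can hold reads of a neighbour.

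On simulated data edgeR recovered 33% of genes changed by a log2 of 0.58 and 75% at 1 for GA/AG against WT (5717 genes), and 58% and 92% for cisplatin against DMSO (5324 genes). It recovered 46% of stop codon changes of a log2 of 2 among 989 genes for GA/AG and 23.5% among 530 genes for cisplatin, and 35.5% and 53.5% of codon position changes of 3. limma recovered 100% of A-site codon changes of 0.8 in both comparisons, and 82% (GA/AG) and 91.5% (cisplatin) of polarity changes of 0.3. In these limma runs the change was added to finished occupancy or polarity values, so reads assigned to a wrong codon were not simulated. They do not tell how often smaller changes would be found.

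Alternatives were DESeq2 1.42.0 size factors and its Wald test, other filters, glmTreat, 1 fit of all 8 libraries, the replicate number as a block, stricter read minima, capped positions, frame 0 reads, another body, camera with an estimated correlation, fry, and leaving out each library in turn. With 1 library left in a group, edgeR and limma assume that the lone sample varies like the other group. An estimated correlation leaves camera with the few residual degrees of freedom of 4 libraries, so it has little power, though how often lists would pass was not simulated. The preset correlation takes list members as varying almost independently. Where members vary together between libraries, its p-values are too small. The profile around tryptophan codons, the use of placed reads, the leaving out of genes with few placed reads, wider windows and GG codons without TGG were chosen after seeing the data. Computation used R 4.3.3 and Python 3.11.15.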

Results

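Ribosome profiling reads the mRNA fragments that ribosomes protect from nuclease, so a read marks where a ribosome stood. None of the libraries used here measures mRNA levels, so a change in a gene's footprints can come from its mRNA level or its translation. Libraries were made from the budding yeast Saccharomyces cerevisiae, strain W303, in 2 datasets with 2 groups each and 2 libraries per group. In the purified dataset, cells in galactose medium made 18S rRNA from a plasmid under the GAL7 promoter, tagged with a binding site for the MS2 phage coat protein, and tagged ribosomes were isolated with that protein. Their 18S rRNA was either wild type (WT) or carried the substitutions G1645A and A1754G (GA/AG). In the other dataset, cells in glucose medium received either 600 µM cisplatin, a platinum drug that binds neighbouring guanines, or its vehicle (1% DMSO) for 1 h, and ribosomes of the whole lysate were used. The gene tables held 9587125 and 10566159 reads for WT, 7531012 and 3758217 for GA/AG, 5632478 and 8047437 for DMSO, and 1737727 and 7573445 for cisplatin. Replicates correlated across genes with r of 0.988 (WT), 0.975 (GA/AG), 0.992 (DMSO) and 0.979 (cisplatin). No label states that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

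The series title names ribosome collisions and competition between ribosomes as its subject. The first comparison asks which mRNAs, and which places on them, GA/AG ribosomes occupied relative to WT ribosomes. Cytosolic ribosomal protein genes lost footprints on GA/AG ribosomes (130 of 135 down), with RPL39 falling by 2.19 ± 0.08 (SE) and RPL41A at -2.15 ± 0.08 on the log2 scale (n = 2 libraries per group). Mitochondrially encoded genes also fell (8 of 8), as in COX2, a subunit of cytochrome c oxidase, at -2.63 ± 0.11, and so did PHO5, a secreted acid phosphatase, at -2.85 ± 0.25. Both list shifts did not pass with an estimated correlation (adjusted p = 0.582 for each). With 2 libraries per group that version passed 0 of 25 lists and has little power, so it does not decide. Of 39 general stress genes 24 rose and 4 fell, and of 33 heat shock genes 20 rose and 3 fell, while the stress and heat shock shifts were lost in the same way (adjusted p = 0.709 and 0.717). Risers included ALD3, an aldehyde dehydrogenase (1.597 ± 0.10), and SSA4, a heat-inducible Hsp70 chaperone (1.14 ± 0.09). Of 5717 genes tested, 696 rose and 882 fell, and 96 of the rises and 332 of the falls were at least 2-fold. Tested against a fold of 1.5 with edgeR's glmTreat, 83 genes rose and 344 fell.

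Among the 8 genes that the naming rule took for the largest rises, ALD3 alone had coding-sequence reads in the position tables to match its gene reads (1059 and 526 with GA/AG, 350 and 365 with WT). ATF1, an alcohol acetyltransferase, rose by 2.93 ± 0.70 (edgeR adjusted p = 0.008), but 264 of its reads lay in GA/AG replicate 2 against 63 in GA/AG replicate 1. Without GA/AG replicate 2 its change was 0.80 and the call was lost. TEL1, a kinase of the DNA damage checkpoint, rose by 2.05 ± 0.17 in the gene tables with 218956 and 159445 reads on GA/AG ribosomes, of which the position tables placed 39 and 23 in its coding sequence. With placed reads, TEL1 stood at -0.09 and SAE2, an endonuclease cofactor, at -0.27, against 1.91 ± 0.30 for SAE2 in the gene tables. YJL213W (1.93 ± 0.22), YMR244W (1.88 ± 0.49), YOR343W-B (1.797 ± 0.49) and YEH1, a steryl ester hydrolase (1.63 ± 0.34), also had almost no placed reads, so their rises are uncertain. Without GA/AG replicate 2, YMR244W stood at 0.87 and YOR343W-B at 0.50, both no longer past the threshold. The largest falls were those of AI5_BETA (-2.97 ± 0.23), AI3 (-2.96 ± 0.22), PHO5, COB, which encodes cytochrome b (-2.74 ± 0.18), BI4 (-2.71 ± 0.37), COX2, BI3 (-2.56 ± 0.31) and Q0255 (-2.52 ± 0.18). Apart from PHO5 these are mitochondrially encoded. AI5_BETA, AI3, BI4 and BI3 are encoded by introns of COX1 or COB and overlap them, and the counting does not say how shared reads were treated. Of the 4 genes named in any case, GCN4, the activator of amino acid synthesis genes, fell (-0.36 ± 0.08, adjusted p = 0.00524) and GAL7, whose promoter drove the plasmid rRNA, rose (0.27 ± 0.08, adjusted p = 0.0236). HEL2, the ligase that senses collided ribosomes, stood at 0.07 ± 0.14 (adjusted p = 0.775) and RPL3 at -0.23 ± 0.08 (adjusted p = 0.0583), both not past the threshold. RPL3 passed without GA/AG replicate 1 (-0.33), and by the DESeq2 Wald test, with no filter, with at least 100 reads, with all 8 libraries in 1 fit, with placed coding reads and without genes with few placed reads (-0.28 to -0.17, adjusted p from 0.00625 to 0.0414). From codon 51 GCN4 was not past the threshold (-0.26). With the replicate number as a block the GAL7 call was lost (edgeR adjusted p = 0.144).

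Of 135 cytosolic ribosomal protein genes, 0 rose, 130 fell and 5 were not past the threshold (0 and 131 adjusted over the list alone), and the median was -1.33. The camera test against all other genes gave an adjusted p of 5.83e-47 for this list at the preset correlation, and adjusted p = 0.582 with an estimated correlation. The former is too small if members vary together between libraries. Many of these genes have a near-identical copy, so single members are less certain than the list. Ribosome biogenesis genes fell as a list (median -0.32, adjusted p = 5.17e-05; adjusted p = 0.582 with an estimated correlation). Of their 75 members, 3 rose, 23 fell and 49 did not pass (3 and 25 adjusted over the list alone). NHP2, a snoRNP protein, stood at -1.25 ± 0.11 and NSR1, a nucleolar protein, at -1.05 ± 0.10. Mitochondrial ribosomal protein genes moved the other way as a list (median 0.25, adjusted p = 0.00877; adjusted p = 0.765 with an estimated correlation). In that list 31 of 72 rose, 13 fell and 28 did not pass (39 and 15 adjusted over the list alone). MRPL35 stood at 0.88 ± 0.09 and MRPL39 at -0.88 ± 0.09. Leaving out GA/AG replicate 1 ended that call (adjusted p = 0.0911), while leaving out any other library gave 0.00276 to 0.0269. Of 40 translation factor genes, 3 rose, 12 fell and 25 did not pass (3 and 14 adjusted over the list alone), and the list did not shift (median -0.11, adjusted p = 0.156). SUI1 fell by 1.39 ± 0.08 and TIF11 by 0.96 ± 0.08, both initiation factors. Genes of the collision response and ribosome quality control did not shift as a list (median 0.14, adjusted p = 0.16), with 5 up, 4 down and 34 not past among 43 (5 and 3 adjusted over the list alone). The members with the lowest p were RPS31, a ubiquitin fusion with a ribosomal protein (-1.76 ± 0.08), and SKI8, part of the Ski complex (0.68 ± 0.10, but 0.05 and no longer past with placed reads).

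All 8 mitochondrially encoded genes of the list fell (0 up and 8 down adjusted over the list alone), and the median was -1.99 (camera adjusted p = 1.96e-06; adjusted p = 0.582 with an estimated correlation). Together, mitochondrially encoded genes, whose mRNAs tagged cytosolic ribosomes do not translate, took 0.240% ± 0.0167 (SD, n = 2) of gene reads in WT and 0.0727% ± 0.00787 in GA/AG. Of 46 respiration and TCA cycle genes, 14 rose, 20 fell and 12 did not pass (14 and 20 adjusted over the list alone), without a shift of the list (median -0.15, adjusted p = 0.117). ATP15, a small subunit of ATP synthase, fell by 1.69 ± 0.08 and COX7 by 1.25 ± 0.07, though the COX7 call was lost from codon 51 (-1.15, adjusted p = 0.0691). The phosphate regulon fell (median -0.90, adjusted p = 0.00369; adjusted p = 0.582 with an estimated correlation), with 0 of 12 up, 8 down and 4 not past (0 and 8 adjusted over the list alone). VTC1, of the polyphosphate polymerase, stood at -1.39 ± 0.10 and PHO84, a phosphate transporter, at -1.55 ± 0.13. Histone genes fell (median -0.73, adjusted p = 0.000334; adjusted p = 0.582 with an estimated correlation), 9 of 10 down and 1 up by both adjustments (1 and 9 adjusted over the list alone). HTB1 fell by 0.99 ± 0.08 and HHF2 by 0.89 ± 0.07, each with a near-identical copy elsewhere. Ergosterol and drug efflux genes shifted down (median -0.39, adjusted p = 0.0256; adjusted p = 0.582 with an estimated correlation), with 2 of 27 up, 9 down and 16 not past (3 and 9 adjusted over the list alone). ERG25 stood at -1.38 ± 0.16 and ERG11, a sterol demethylase, at -1.46 ± 0.17. From codon 51 ERG11 stood at -0.74 and was not past the threshold. The ergosterol call was lost without WT replicate 2 (adjusted p = 0.0592), without GA/AG replicate 2 (0.0659) and with reads from codon 51 on (0.115), against 0.00906 and 0.0423 without either other library. MATa-specific genes fell (median -0.79, adjusted p = 0.00232; adjusted p = 0.582 with an estimated correlation), with 0 of 7 up, 3 down and 4 not past (0 and 5 adjusted over the list alone), including the pheromone precursors MFA1 (-1.66 ± 0.10) and MFA2 (-1.63 ± 0.08). With reads from codon 51 on the MATa shift was not past the threshold (adjusted p = 0.577), but 5 members could be tested there, since the frames of MFA1 (36 codons) and MFA2 (38 codons) end before it. That loss is not a smaller change of these 2 genes.

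General stress genes controlled by Msn2/4 rose as a list (median 0.42, adjusted p = 2.18e-06; adjusted p = 0.709 with an estimated correlation), 24 of 39 up, 4 down and 11 not past (26 and 5 adjusted over the list alone). ALD3 rose with them and HOR7, a small hyperosmolarity-responsive protein, fell by 0.99 ± 0.09. Heat shock and chaperone genes also rose (median 0.37, adjusted p = 0.000106; adjusted p = 0.717 with an estimated correlation), 20 of 33 up, 3 down and 10 not past (21 and 3 adjusted over the list alone). HSP60 stood at 0.71 ± 0.07. Proteasome genes rose as a list (median 0.17, adjusted p = 0.00574; adjusted p = 0.765 with an estimated correlation), 10 of 36 up, 1 down and 25 not past (13 and 1 adjusted over the list alone). RPT4 stood at 0.60 ± 0.09 and RPT1 at 0.58 ± 0.10. Leaving out GA/AG replicate 1 ended the proteasome call (adjusted p = 0.107, against 0.000473 to 0.0219 without any other library). Gcn4 targets did not pass (median 0.10, adjusted p = 0.0627), with 13 of 52 up, 3 down and 36 not past (13 and 3 adjusted over the list alone). HIS1 stood at 0.60 ± 0.08 and ARG3 at 0.62 ± 0.09. Without WT replicate 2 or GA/AG replicate 2 this list passed (adjusted p = 0.0447 and 0.0273, against 0.107 and 0.173 without either other library). It also passed with placed coding reads (median 0.17, adjusted p = 0.00243) and from codon 51 (0.00266). DNA damage genes did not shift (median 0.04, adjusted p = 0.872), with 4 of 35 up, 5 down and 26 not past (4 and 5 adjusted over the list alone), UBC13 at -0.47 ± 0.09 and RAD16 at 0.72 ± 0.15.

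Yap1 targets of oxidative stress (6 of 33 up, 5 down and 22 not past; 7 and 5 adjusted over the list alone) had a median of -0.01 while camera placed them upward (adjusted p = 0.898), so median and test differ in sign. ZWF1 rose by 0.87 ± 0.08 there and TRX3 fell by 1.21 ± 0.09. Sulfur and methionine genes (2 of 33 up, 4 down, 27 not past; 2 and 2 adjusted over the list alone) did not shift (median -0.08, adjusted p = 0.723). MET32 stood at 0.89 ± 0.19 and MET30 at 0.69 ± 0.15, but with placed reads MET30 stood at -0.22 and MET32 at 0.62, not past the threshold. In galactose metabolism (2 of 11 up, 1 down, 8 not past; 3 and 1 adjusted over the list alone; adjusted p = 0.774, median 0.04), PGM2 stood at 0.51 ± 0.08 and the transporter GAL2 at -0.63 ± 0.08. Glycolysis and fermentation (0 of 23 up, 3 down, 20 not past; 0 and 3 adjusted over the list alone) gave an adjusted p of 0.898 and a median of -0.01, with the glucose transporters HXT6 at -1.80 ± 0.19 and HXT7 at -1.18 ± 0.27, which are near-identical to each other (HXT7 -1.11 and not past without WT replicate 1). From codon 51 HXT6 stood at -0.31 and was not past the threshold. The iron and copper list (0 of 22 up, 1 down, 21 not past; 0 and 1 adjusted over the list alone; median 0.44, adjusted p = 0.385) had CRS5, a metallothionein, at -1.04 ± 0.08 and SMF3 at 1.20 ± 0.43 (adjusted p = 0.0563, and past the threshold at 1.61 without GA/AG replicate 1). With placed coding reads SMF3 stood at -0.23 and from codon 51 at -0.64, so its rise is uncertain. The median of the list was then -0.17, and 0.18 from codon 51 on 11 members, so its direction is open. Cell wall genes (2 of 26 up, 4 down, 20 not past; 1 and 4 adjusted over the list alone; median -0.09, adjusted p = 0.461) included GAS1 at -1.17 ± 0.11 and CWP1 at 0.63 ± 0.08. For cell cycle and mating response genes (1 of 23 up, 4 down, 18 not past; 1 and 4 adjusted over the list alone) the median was 0.02, the mean was -0.04 and camera pointed upward (adjusted p = 0.898), with the chitinase CTS1 at -0.65 ± 0.10 and the cyclin PCL2 at -0.95 ± 0.19. With placed coding reads CTS1 stood at -0.35, and PCL2 at -0.36 and not past the threshold. From codon 51 CTS1 stood at 0.19 (adjusted p = 0.569), so its call was lost and its sign turned. MATalpha-specific genes (0 of 4 up, 1 down, 3 not past; 0 and 1 adjusted over the list alone) had a median of 0.00, a mean of -0.55 and a downward camera direction (adjusted p = 0.871). With placed coding reads and from codon 51 that list passed (adjusted p = 0.0461 and 0.0403), the latter on 2 genes, while MF(ALPHA)1 did not pass (-2.496, adjusted p = 0.0503, and -2.41, adjusted p = 0.0691). MF(ALPHA)1 stood at -2.41 ± 0.78 on 32, 37, 7 and 1 reads, and was not past the threshold without WT replicate 1 (-2.47), WT replicate 2 (-2.37) or GA/AG replicate 2 (-1.95), and SAG1 at 0.20 ± 0.34. Of 14 sporulation genes, 0 rose and 0 fell by edgeR after either adjustment (0 and 0 adjusted over the list alone; median -0.15, camera adjusted p = 0.871), with SSP1 at -0.55 ± 0.23 and IME1 at 0.46 ± 0.22. IME1, an activator of meiosis, passed with placed coding reads (0.91) and from codon 51 (0.87). From codon 51 the medians of the DNA damage (-0.03), Yap1 (0.10), glycolysis (0.10) and cell wall (0.03) lists had the opposite sign, none past the threshold. Over all 25 lists, 4 rose and 7 fell by camera. With estimated correlations camera called 0 lists, 1 had an unadjusted p under 0.05, and fry called 10.

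**Figure D1:**
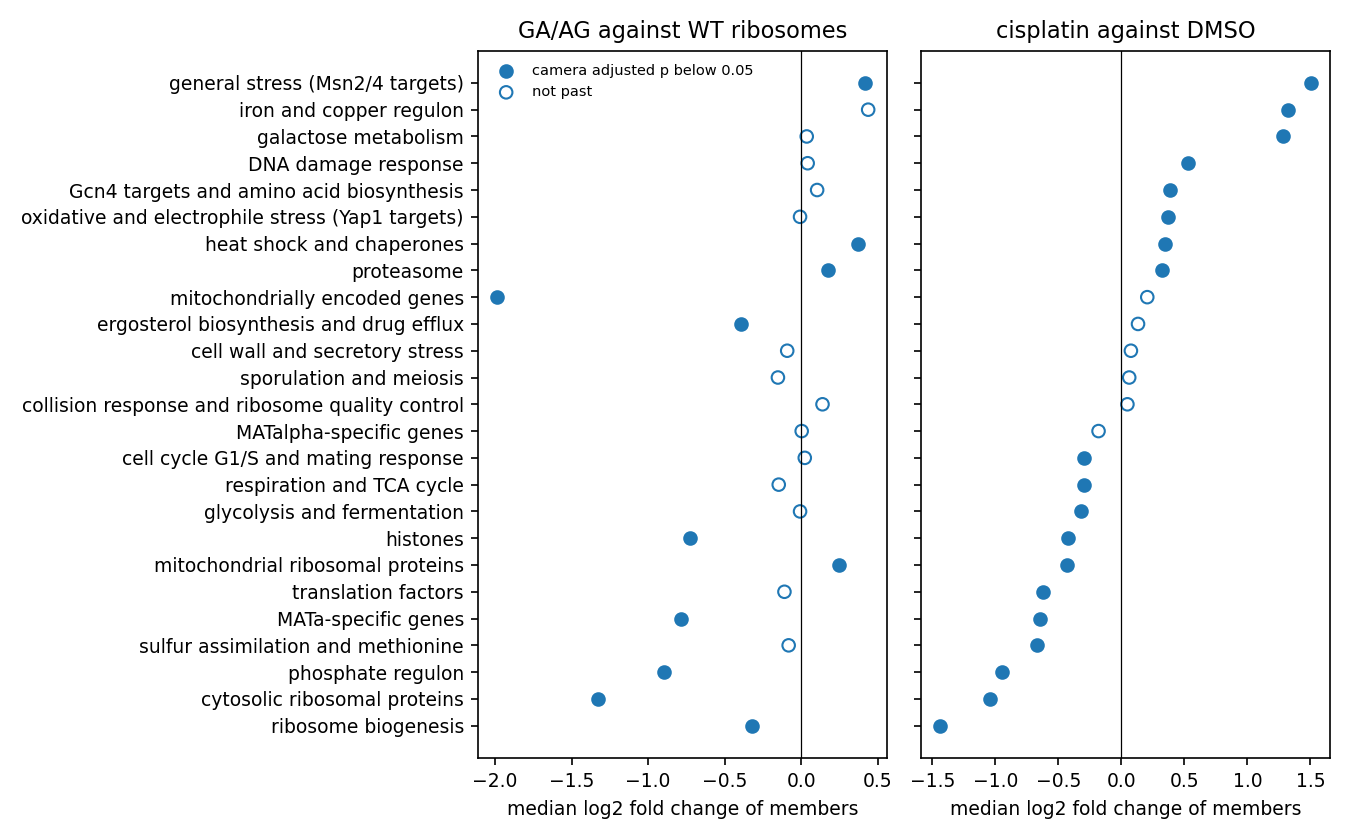
Median log2 fold change of the members of each of the 25 gene lists, with GA/AG against WT on the left and cisplatin against DMSO on the right. Filled circles mark lists past the camera threshold and open circles the others, and cytosolic ribosomal proteins lie at -1.33 and -1.04.

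**Figure D2:**
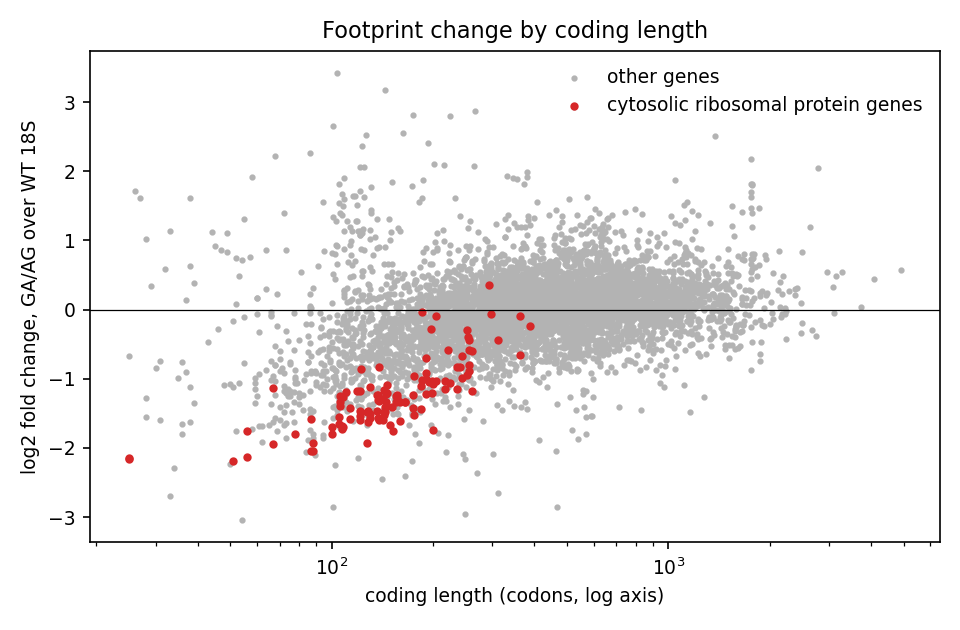
Log2 fold change of each gene (GA/AG over WT) against its coding length in codons on a log axis, with cytosolic ribosomal protein genes in red and other genes in grey. The Spearman correlation across genes was 0.359 for the other genes and 0.780 for the ribosomal protein genes.

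Along the mRNA, GA/AG ribosomes had fewer reads in the start and stop codon windows (2 codons each) relative to the coding body of the same genes from codon 51. Mean relative density at the start codon was 4.55 ± 0.216 (SD, n = 2) in WT and 2.54 ± 0.0605 in GA/AG, and at the stop codon 3.799 ± 0.0246 and 1.69 ± 0.0417. By edgeR with each gene's body reads as offset, 95 of 1164 genes fell at the start codon and 0 rose (284 at an unadjusted p under 0.05), including the cell wall genes CCW12 (-0.80 ± 0.17) and CWP2 (-0.68 ± 0.17). At the stop codon, 57 of 989 fell and 0 rose (268 unadjusted), with the peroxiredoxin TSA1 at -1.01 ± 0.26 and the enolase ENO2 at -1.05 ± 0.29, while HAP4 went from 33 and 24 reads to 0 and 0. In codons 3 to 50 the density was 1.605 ± 0.00426 in WT and 1.26 ± 0.0413 in GA/AG, with 238 of 1937 genes down and 4 up. The 4, named after their values were seen, were RSM25 (0.87 ± 0.27), ECM15 (0.48 ± 0.14), SML1 (0.35 ± 0.12) and COX26 (0.26 ± 0.09). Rises there numbered 1 without WT replicate 1, 1 without WT replicate 2, 9 without GA/AG replicate 1 and 2 without GA/AG replicate 2, so most of the 4 calls were lost when 1 WT library was left out. The 5' UTR window went from 0.207 ± 0.00375 to 0.125 ± 0.00289, a difference of -0.0824, against -0.0538 in genes with at least 500 body reads. There 4 of 443 genes passed, all down: ZEO1 (-1.40 ± 0.29), TDH3 (-1.92 ± 0.31), YDR524C-B (-2.13 ± 0.37) and RNR2 (-4.11 ± 0.67), with 0 up and 77 at an unadjusted p under 0.05. The 3' UTR window went from 0.0496 ± 0.000802 to 0.0286 ± 0.0012, a difference of -0.0210 that was only -0.0025 in genes with at least 500 body reads, so that fall is not firm. In this window CYC1 rose (1.47 ± 0.20, adjusted p = 2.39e-08) and CCW12 (-0.95 ± 0.26) and GAL10 (-3.60 ± 1.00) fell among 224 genes. CYC1 alone held 2687 and 3544 reads in WT and 6963 and 3072 in GA/AG. All 1328 genes of this window together held 10229 and 11215, and 10689 and 4708. The origin of the CYC1 reads was not tested, so they need not be ribosomes past its stop codon. The CYC1 call was lost without GA/AG replicate 1 and without GA/AG replicate 2, where 0 genes rose, and both falls were lost without WT replicate 1 and without WT replicate 2, where 0 genes fell. The counts moved with single libraries. Without WT replicate 1, WT replicate 2, GA/AG replicate 1 and GA/AG replicate 2 in turn, start codon calls numbered 41, 40, 1 and 0, stop codon calls 24, 26, 156 and 97, early coding calls 85, 94, 241 and 179, 5' UTR calls 3, 2, 0 and 0, and 3' UTR calls 1, 1, 4 and 2.

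**Figure D3:**
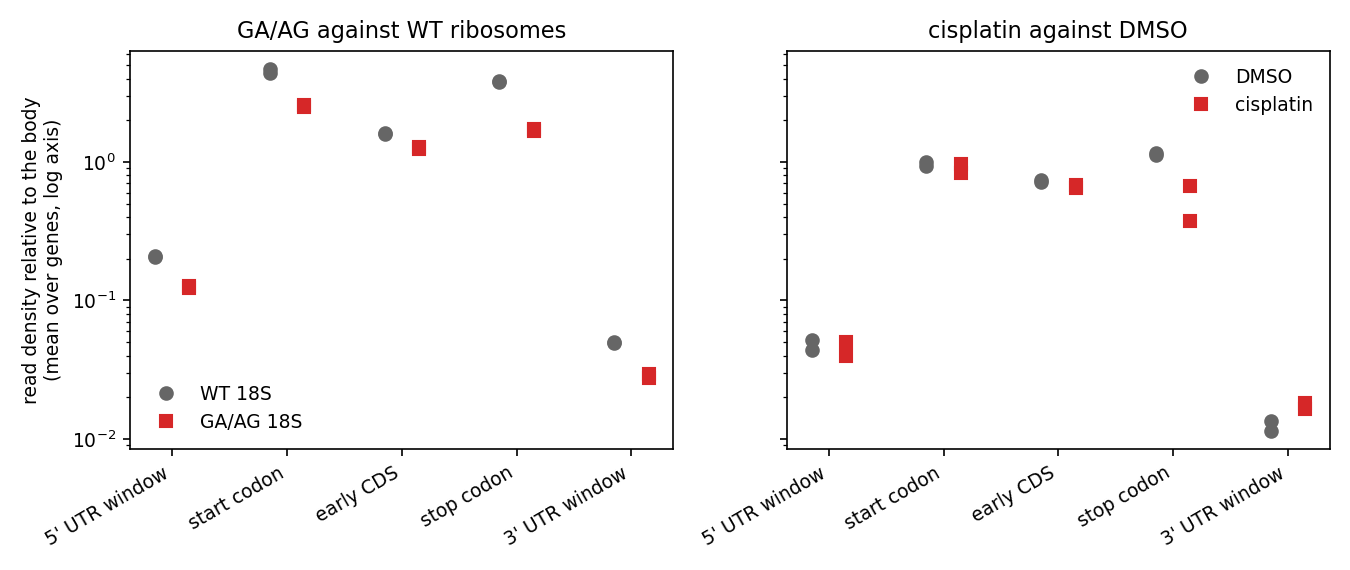
Mean read density in each window relative to the coding body of the same genes, on a log axis, with 1 point per library. In the left panel both GA/AG libraries lie below both WT libraries in every window; in the right panel the stop codon values of cisplatin (0.675 and 0.375) lie below those of DMSO (1.17 and 1.11).

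By limma on 61 codons, 0 codons changed in the A site, where the next amino acid is decoded (2 at an unadjusted p under 0.05), and 0 in the P site (7 unadjusted). CGA, a rare arginine codon, stood at 0.18 ± 0.03 in the A site (adjusted p = 0.125, and -0.24 with at least 500 body reads), and TGG, the tryptophan codon, at -0.17 ± 0.04 in the P site (adjusted p = 0.0629, past the threshold with capped positions and with the replicate number as a block). Leaving out GA/AG replicate 1 gave 3 P-site codons and leaving out GA/AG replicate 2 gave 6, against 0 without either WT library. CTC (0.15 ± 0.04), CAT (-0.14 ± 0.04), CCC (-0.13 ± 0.04) and ATA (0.12 ± 0.03) did not pass in the P site, nor did CTC (0.11 ± 0.05), CCG (0.09 ± 0.04), GGC (-0.10 ± 0.03) and GGT (-0.08 ± 0.03) in the A site. In the E site CGA alone passed (-0.25 ± 0.05, adjusted p = 0.000303), and the call was lost without WT replicate 2 (-0.20), without GA/AG replicate 2 (-0.19), with at least 500 body reads (-0.06), with the replicate number as a block, and with frame 0 reads alone, where the change was -0.03. Codons holding GG had a mean log2 occupancy of 0.33 over other codons in each WT library and 0.29 in each GA/AG library at the A site. By edgeR, 0 of 114337 single codon positions changed, with 5404 at an unadjusted p under 0.05, and leaving out GA/AG replicate 2 or WT replicate 2 gave 3 and 1. Polarity, which measures whether reads lie toward the 5' or 3' end, changed in 0 of 2232 genes by limma (232 unadjusted), and in 11 with at least 500 body reads, 9 of them toward the 3' end. The share of body reads in frame 0 was 46.7% ± 2.51 in WT and 48.0% ± 2.28 in GA/AG (two-sided exact permutation p = 0.667, where the smallest possible is 0.33). Frame 1 held 25.6% and 32.9% in WT replicates 1 and 2, and 31.8% and 23.4% in GA/AG replicates 1 and 2. By frame, WT replicate 1 thus resembled GA/AG replicate 2, and WT replicate 2 resembled GA/AG replicate 1. With at most 49.6% in frame 0, reads may count toward a neighbouring codon, so the absence of codon calls does not exclude changes.

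The second comparison asks how 1 h of cisplatin changed footprints in whole cells. The largest rises of single genes included the siderophore transporter ARN2 (5.53 ± 0.22, adjusted p = 5.46e-09), the cell wall mannoproteins FIT3 (4.63 ± 0.13) and FIT2 (4.42 ± 0.10), and TIS11, which promotes decay of mRNAs of iron-using proteins (3.48 ± 0.14; n = 2 libraries per group). Ribosome biogenesis genes fell, with NSR1 at -2.56 ± 0.07, and all 75 measured members were down. Every one of 39 measured Msn2/4 stress genes rose, and 133 of 135 cytosolic ribosomal protein genes fell. These 3 list shifts did not pass with an estimated correlation (adjusted p = 0.117, 0.117 and 0.164). That version passed 0 of 25 lists here too and has little power with so few libraries, so it does not decide. At tryptophan codons, occupancy in the A site rose from 5.77 to 10.1 times the gene mean. By edgeR, 1218 of 5324 genes rose and 1350 fell, of which 353 and 395 were at least 2-fold. Requiring at least 100 reads in every library left 801 up and 821 down, and testing against a fold of 1.5 gave 392 up and 524 down.

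The remaining large rises were TMA10, a ribosome-associated protein (3.74 ± 0.15), PHM7 (3.68 ± 0.15), the hexose transporter HXT5 (3.63 ± 0.24) and FMP45, a membrane protein (3.56 ± 0.28). HXT5, whose family shares sequence, stood at 1.28 with placed coding reads. The largest falls were the alcohol dehydrogenase ADH4 (-3.05 ± 0.09, adjusted p = 1.06e-09), TOD6, a repressor of ribosome biogenesis genes (-2.85 ± 0.24), DHR2, an RNA helicase (-2.71 ± 0.23), the rRNA methyltransferase BMT6 (-2.57 ± 0.27), NSR1, the adenine deaminase AAH1 (-2.52 ± 0.12), SSF1, a ribosome assembly factor (-2.45 ± 0.16), and RFU1 (-2.39 ± 0.27). GCN4 rose by 1.56 ± 0.06 (adjusted p = 5.81e-09) and RPL3 fell by 0.81 ± 0.05 (adjusted p = 7.71e-08). HEL2 stood at -0.14 ± 0.10 (adjusted p = 0.279), and GAL7 was too low to test, with 3, 8, 2 and 16 reads.

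Cytosolic ribosomal protein genes (0 up, 133 down and 2 not past; 0 and 133 adjusted over the list alone) had a median of -1.04 (camera adjusted p = 2.44e-32; adjusted p = 0.164 with an estimated correlation), with RPS22A at -1.52 ± 0.05 and RPL9A at -1.50 ± 0.05, both with near-identical copies. Ribosome biogenesis genes (0 up and 75 down; 0 and 75 adjusted over the list alone) had a median of -1.44 (adjusted p = 1.37e-26; adjusted p = 0.117 with an estimated correlation), with NOP56, a snoRNP core protein, at -1.23 ± 0.06. Mitochondrial ribosomal protein genes fell too (median -0.44, adjusted p = 1.62e-09; adjusted p = 0.117 with an estimated correlation), 53 of 72 down, 1 up and 18 not past (1 and 58 adjusted over the list alone). MRPL23 stood at -0.87 ± 0.10 and MRP8, which rose, at 0.83 ± 0.07. The list takes its members by name alone, so whether MRP8 belongs in it is uncertain. Translation factors fell (median -0.62, adjusted p = 9.28e-11; adjusted p = 0.117 with an estimated correlation), 35 of 40 down, 0 up and 5 not past (0 and 39 adjusted over the list alone). The elongation factor YEF3 stood at -1.12 ± 0.04 and EFB1 at -1.44 ± 0.05. Genes of the collision response and ribosome quality control went both ways (14 of 43 up, 9 down, 20 not past; 14 and 9 adjusted over the list alone) without a shift (median 0.05, adjusted p = 0.6). ASC1, a ribosomal scaffold protein, fell by 0.70 ± 0.04 and RPS31 by 0.99 ± 0.04. Sulfur and methionine genes fell (median -0.67, adjusted p = 2e-05; adjusted p = 0.134 with an estimated correlation), 23 of 32 down, 4 up and 5 not past (4 and 24 adjusted over the list alone). The sulfate adenylyltransferase MET3 stood at -2.19 ± 0.06 and MET6 at -0.88 ± 0.03.

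The phosphate regulon fell (median -0.95, adjusted p = 0.00518; adjusted p = 0.164 with an estimated correlation), 10 of 13 down, 1 up and 2 not past (1 and 10 adjusted over the list alone). PHO84 stood at -0.95 ± 0.05 and PHM8, the riser, at 1.57 ± 0.09. Glycolysis genes fell (median -0.32, adjusted p = 0.00518; adjusted p = 0.261 with an estimated correlation), 15 of 22 down, 1 up and 6 not past (1 and 15 adjusted over the list alone). ENO2 stood at -0.81 ± 0.03 and PDC1 at -0.59 ± 0.03. Respiration genes fell (median -0.30, adjusted p = 0.00872; adjusted p = 0.164 with an estimated correlation), 28 of 46 down, 8 up and 10 not past (9 and 30 adjusted over the list alone). The cytochrome c isoforms parted, at -1.23 ± 0.06 for CYC1 and 1.66 ± 0.13 for CYC7, which stood at 0.72 from codon 51. Cell cycle and mating response genes fell (median -0.30, adjusted p = 0.00973; adjusted p = 0.254 with an estimated correlation), 9 of 23 down, 0 up and 14 not past (0 and 9 adjusted over the list alone), including the pheromone arrest factor FAR1 (-1.34 ± 0.10) and the cyclin CLB2 (-0.84 ± 0.10). MATa-specific genes fell (median -0.64, adjusted p = 0.0132; adjusted p = 0.261 with an estimated correlation), 6 of 7 down, 0 up and 1 not past (0 and 6 adjusted over the list alone). STE2 stood at -0.75 ± 0.06 and BAR1 at -0.85 ± 0.07. Histone genes shifted down (median -0.42, adjusted p = 0.0185; adjusted p = 0.383 with an estimated correlation), 7 of 10 down, 1 up and 2 not past (1 and 7 adjusted over the list alone). HHF1 stood at -0.76 ± 0.06 and HHF2 at -0.63 ± 0.06. From codon 51 they stood at -0.11 (HHF1, not past the threshold) and -0.18 (HHF2). The histone call was lost with reads placed in the coding sequence (adjusted p = 0.105), with those from codon 51 on (0.273) and without cisplatin replicate 2 (0.0715, against 0.0149 to 0.0391 without any other library).

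Msn2/4 genes (39 up, 0 down; 39 and 0 adjusted over the list alone) had a median of 1.51 (adjusted p = 1.75e-17; adjusted p = 0.117 with an estimated correlation), with PGM2 at 1.94 ± 0.07 and the trehalose synthase subunit TSL1 at 1.93 ± 0.07. The iron and copper regulon rose (median 1.32, adjusted p = 9.1e-07; adjusted p = 0.164 with an estimated correlation), 15 of 21 up, 2 down and 4 not past (15 and 2 adjusted over the list alone). Gcn4 targets rose (median 0.39, adjusted p = 2.97e-05; adjusted p = 0.134 with an estimated correlation), 35 of 52 up, 9 down and 8 not past (36 and 9 adjusted over the list alone). ARG1 stood at 1.49 ± 0.05 and TMT1 at 2.82 ± 0.09. DNA damage genes rose (median 0.53, adjusted p = 3.77e-05; adjusted p = 0.134 with an estimated correlation), 20 of 34 up, 2 down and 12 not past (20 and 2 adjusted over the list alone). The checkpoint kinase DUN1 stood at 1.19 ± 0.11. Proteasome genes rose (median 0.32, adjusted p = 3.5e-06; adjusted p = 0.134 with an estimated correlation), 29 of 36 up, 0 down and 7 not past (29 and 0 adjusted over the list alone). Their activator RPN4 stood at 0.90 ± 0.10 and RPT3 at 0.70 ± 0.07. Yap1 targets rose (median 0.37, adjusted p = 0.00717; adjusted p = 0.164 with an estimated correlation), 17 of 32 up, 4 down and 11 not past (19 and 4 adjusted over the list alone). GRE2 stood at 1.19 ± 0.08 and the glutaredoxin GRX2 at 0.96 ± 0.08. Galactose genes shifted up (median 1.29, adjusted p = 0.0423; adjusted p = 0.304 with an estimated correlation), 4 of 8 up, 0 down and 4 not past (4 and 0 adjusted over the list alone). The reductase GCY1 stood at 1.66 ± 0.13 beside PGM2. Without DMSO replicate 2 the galactose call was lost (adjusted p = 0.0638, against 0.0178 to 0.0339 without any other library). Heat shock genes shifted up (median 0.34, adjusted p = 0.0429; adjusted p = 0.296 with an estimated correlation), 16 of 33 up, 11 down and 6 not past (16 and 11 adjusted over the list alone). The disaggregase HSP104 stood at 1.62 ± 0.06 and HSP78 at 1.70 ± 0.06. The heat shock call was lost without cisplatin replicate 1 (adjusted p = 0.0903), without cisplatin replicate 2 (0.0514) and with placed reads (median 0.07, adjusted p = 0.138), against 0.0268 and 0.017 without either DMSO library.

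Mitochondrially encoded genes did not shift (2 of 7 up, 0 down, 5 not past; 2 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.254), with COX2 at 1.21 ± 0.23 and COX3 at 0.74 ± 0.24. The COX3 call was lost without DMSO replicate 1 (change 0.90), DMSO replicate 2 (0.54) and cisplatin replicate 2 (0.54). Ergosterol and drug efflux genes moved both ways (10 of 27 up, 8 down, 9 not past; 10 and 8 adjusted over the list alone; median 0.13, adjusted p = 0.6), with ERG11 at -0.72 ± 0.06 and ERG2 at -0.66 ± 0.08. Cell wall genes (11 of 26 up, 4 down, 11 not past; 12 and 4 adjusted over the list alone; median 0.08, adjusted p = 0.171) included the glucan synthase GSC2 at 2.06 ± 0.07 and the protease YPS1 at 1.88 ± 0.07. Of 3 MATalpha-specific genes, MF(ALPHA)1 passed (-2.73 ± 0.79, on 12, 21, 0 and 4 reads; 0 up and 1 down adjusted over the list alone) and SAG1 stood at 0.18 ± 0.48, and the list did not shift (median -0.18, and 0.26 with placed coding reads; adjusted p = 0.629). Of 10 sporulation genes, 1 rose, SPS100 (2.09 ± 0.64), 36 of whose reads lay in cisplatin replicate 2, and 0 rose or fell adjusted over the list alone (median 0.06, adjusted p = 0.629). DIT1 stood at 1.59 ± 0.65 and passed without cisplatin replicate 2 (2.34). MF(ALPHA)1 did not pass without DMSO replicate 2 (-2.58, adjusted p = 0.054) or cisplatin replicate 2 (adjusted p = 0.0605), the latter with 0 reads left in cisplatin, so that loss is not a smaller change. Without DMSO replicate 1, DMSO replicate 2 or cisplatin replicate 2 the SPS100 change was 2.01, 2.09 and 0.96 and not past the threshold. Over the 25 lists camera called 8 up and 11 down. With estimated correlations it called 0, with 8 at an unadjusted p under 0.05, and fry called 21.

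In the A site, 2 of 61 codons rose and 21 fell with cisplatin by limma. Occupancy is relative to each gene's mean, which TGG reads raise, and the median change of all codons was -0.0821, so the falls carry this shift. TGG (tryptophan) rose by 0.81 ± 0.05 (adjusted p = 0.000425, higher in both cisplatin libraries than in either DMSO library) and CCG (proline) by 0.34 ± 0.07 (adjusted p = 0.0173). With at least 500 body reads CCG stood at 0.18 (adjusted p = 0.115) and CGC at -0.37 (adjusted p = 0.0562), both not past the threshold. The largest falls were CAC (-0.42 ± 0.06), CGC (-0.33 ± 0.06), GTG (-0.32 ± 0.03) and AGG (-0.31 ± 0.06). Without DMSO replicate 1 no codon passed (0 of 61) and without DMSO replicate 2 only 1 did, TGG, while without cisplatin replicate 1 and 2 the counts were 33 and 28. The TGG change was 0.80 without DMSO replicate 1 (adjusted p = 0.0507), and over all alternatives it lay between 0.62 and 0.86 with adjusted p from 3.08e-25 to 0.0507. Codons holding GG, not tested for a change, had a mean log2 occupancy over other codons of 1.14 ± 0.0189 (SD) in DMSO and 1.55 ± 0.0642 in cisplatin, and without TGG 0.62 ± 0.0194 and 0.61 ± 0.0394. In the P site 0 codons passed by limma (12 unadjusted), TGG standing at 0.38 ± 0.27, with 1.12 in cisplatin replicate 2 against 0.38 in cisplatin replicate 1, and leaving out cisplatin replicate 1 gave 1 codon, TGG. In the E site CGG fell by 0.47 ± 0.09 (adjusted p = 0.0424), a call lost without DMSO replicate 1 (-0.32), cisplatin replicate 1 (-0.44) or cisplatin replicate 2 (-0.51), and from codon 51 (-0.45). Other codons named by the rule did not pass, among them TCA (0.19 ± 0.03), ATT (-0.17 ± 0.05) and GGG (-0.16 ± 0.02) in the P site and TCG (-0.29 ± 0.07) in the E site. TCG passed there with the replicate number as a block (adjusted p = 3.17e-05), and stood at 0.02 with frame 0 reads alone.

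**Figure D4:**
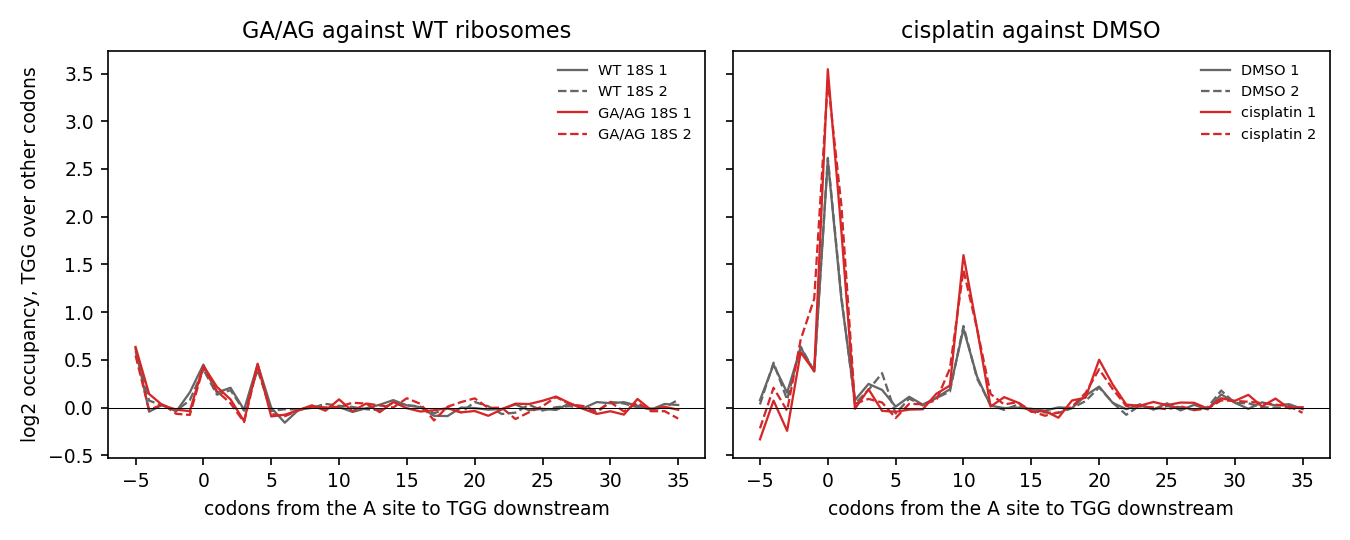
Log2 occupancy of positions at each distance from a tryptophan codon relative to other codons, per library, by the number of codons from the A site to the TGG downstream. In the right panel both cisplatin libraries reach 3.54 and 3.43 at distance 0 and 1.597 and 1.44 at distance 10, above DMSO at 2.59 and 2.62, and 0.82 and 0.85.

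Of 123867 single codon positions in 1903 genes, 833 rose (in 361 genes) and 329 fell (in 129 genes) by edgeR. Tryptophan codons made up 355 of the rises, 6.22% of the 5709 TGG positions tested, and 0 of the falls. The largest rises were codon 316 of the aldose reductase GRE3, a TGG with 0 and 0 reads in DMSO and 14 and 12 in cisplatin, codon 415 of ARG7 (0 and 0, then 10 and 22), codon 1052 of YBT1 (1 and 0, then 71 and 0) and codon 64 of RER1 (0 and 0, then 0 and 34). The largest falls were codon 590 of WHI4 (0 and 44 reads, then 0 and 0), codon 198 of the chaperone SSE1 (21 and 14, then 0 and 0), codon 147 of LYS12 (18 and 19, then 0 and 0) and codon 492 of INA1 (15 and 26, then 0 and 0). YBT1, RER1 and WHI4 each rest on 1 library. Calls numbered 28 without DMSO replicate 1, 8 without DMSO replicate 2, 3957 without cisplatin replicate 1 and 2516 without cisplatin replicate 2. The frame 0 share of body reads was 78.2% ± 0.305 in DMSO and 77.5% and 70.3% in the cisplatin libraries (two-sided exact permutation p = 0.33, the smallest possible).

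Relative density at the stop codon was 1.14 ± 0.0370 in DMSO and 0.525 ± 0.212 in cisplatin, where the libraries gave 0.675 and 0.375. By edgeR 0 of 530 genes changed there, with 178 at an unadjusted p under 0.05 and 92.6% of genes below 0. That 0 is not firm, since 64 genes fell with at least 500 body reads, and 95 fell and 1 rose with the window 3 nt wider. Without cisplatin replicate 1 the stop codon count was 262 and without cisplatin replicate 2 it was 15, against 0 without either DMSO library. The start codon window gave 0.965 ± 0.0401 and 0.899 ± 0.102, with the actin-binding profilin PFY1 up (2.29 ± 0.29, adjusted p = 2.04e-12) among 679 genes. Without cisplatin replicate 1 and 2 in turn, 4 and 14 genes passed at the start codon, and 0 did with at least 500 body reads, a setting that tests fewer genes. In codons 3 to 50 the density was 0.731 ± 0.0126 and 0.663 ± 0.0218, with 9 of 1725 genes up, such as the cell wall protein CIS3 (0.97 ± 0.13) and RPL24A (0.90 ± 0.13), and 8 down, such as YEF3 (-1.19 ± 0.15) and TEF1 (-0.88 ± 0.08). Without DMSO replicate 1 the early coding calls were 0 up and 6 down, so the CIS3 and RPL24A calls were lost, and without DMSO replicate 2 they were 1 up and 3 down. The early coding count was 124 and 126 without cisplatin replicate 1 and 2. In the 5' UTR window (0.0481 ± 0.00558 and 0.0448 ± 0.00716) CWP2 rose (2.59 ± 0.30) and PDR16 fell (-2.93 ± 0.37) among 146 genes, with 4 calls without DMSO replicate 1, 0 up and 2 down without DMSO replicate 2, so the CWP2 call was lost, and 0 calls without cisplatin replicate 1 or 2. In the 3' UTR window (0.0125 ± 0.00148 and 0.0173 ± 0.0012) the density difference had the opposite sign with at least 500 body reads (-0.000859), and the median log2 change of 0.25 became -0.55 without cisplatin replicate 2, so its direction is open. HAP1 rose (2, 0, 4 and 22 reads), and CCW12 (-0.62 ± 0.08) and LSP1 (1, 23, 0 and 3 reads) fell among 46 genes, with 0 up and 2 down without DMSO replicate 1, so the HAP1 call was lost, and 0 calls without DMSO replicate 2 or cisplatin replicate 2. Genes named here for a window were named after their values were seen. Polarity changed in 0 of 1935 genes by limma (367 unadjusted), with medians of 0.0472 ± 7.86e-05 in DMSO and 0.0773 ± 0.00258 in cisplatin, and 1 and 6 genes passed without DMSO replicate 1 and without cisplatin replicate 2. With at least 500 body reads 80 genes passed, 69 toward the 3' end and 11 toward the 5' end.

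Log2 fold changes of the 2 comparisons, which share no library, correlated across 5305 genes with Pearson's r of 0.301 and Spearman's rho of 0.314, where genes are not independent replicates. Both comparisons raised 287 genes (152 by independent lists) and lowered 467 (218 by independent lists), while 98 rose with GA/AG and fell with cisplatin and 92 did the reverse. Without cytosolic ribosomal protein genes r was 0.241, and with at least 100 reads in all 8 libraries it was 0.470. Changes of the 61 A-site codons did not go together (r of 0.00645, and 0.0226 without TGG).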

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

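Alternatives with placed reads, a wider window or GG codons without TGG were chosen after seeing the data. Of 2194 values of named genes and codons under an alternative, 2052 kept their direction and side of the threshold, 86 lost it, 31 gained it and 25 changed sign. For GA/AG against WT, testing against a fold of 1.5 left 427 genes, because it asks for a larger change, and other gene counts were 1164 to 1770. For cisplatin, 1622 genes passed with at least 100 reads per library (fewer genes tested), 916 against a fold of 1.5, and other counts were 1842 to 2720. Camera with an estimated correlation called 0 lists in each comparison, and with so few libraries it has little power, so these losses do not decide. Genes with at least 500 body reads gave, for GA/AG, 0 E-site codons, 24 genes in the 5' UTR, 87 at the stop codon and 11 for polarity, and, for cisplatin, 2 E-site codons, 1 gene in the 5' UTR, 0 at the start codon, 27 in early coding sequence, 64 at the stop codon and 80 for polarity. The mean density difference of GA/AG was then -0.0538 in the 5' UTR (against -0.0824), -2.51 at the start codon (against -2.01), -1.62 at the stop codon (against -2.11) and -0.0025 in the 3' UTR (against -0.0210), and that of cisplatin in the 3' UTR was -0.000859, the opposite sign. Windows 3 nt wider gave 99 genes at the stop codon for GA/AG, and 96 there and 4 at the start codon for cisplatin. Same-numbered samples deviated with correlations of 0.0147 and -0.0448, so numbers do not pair them; as a block the number gave, for GA/AG, 4 P-site and 0 E-site codons, 2 genes in the 5' UTR, 44 at the start, 21 at the stop, 1 in the 3' UTR and 7 codon positions, and, for cisplatin, 2 E-site codons, 14 genes in the 5' UTR and 745 positions. With that block GAL7 of GA/AG lost its call (0.27, adjusted p = 0.144). Capped positions gave 1 P-site codon for GA/AG, frame 0 reads 0 E-site codons for GA/AG, the body from codon 51 0 E-site codons for cisplatin, and at least 50 reads 595 positions for cisplatin. Leaving out each library gave for GA/AG 0 to 6 P-site and 0 to 1 E-site codons, 0 to 3 genes in the 5' UTR, 0 to 41 at the start, 85 to 241 in early coding sequence, 24 to 156 at the stop, 1 to 4 in the 3' UTR and 0 to 3 positions. For cisplatin it gave 0 to 33 A-site, 0 to 1 P-site and 0 to 1 E-site codons, 0 to 4 genes in the 5' UTR, 1 to 14 at the start, 4 to 126 in early coding sequence, 0 to 262 at the stop, 0 to 4 in the 3' UTR, 0 to 6 for polarity and 8 to 3957 positions. The GG difference at the A site for GA/AG was 0.0451 across codon boundaries (opposite sign), -0.0525 without TGG, -0.0192 at 500 reads and -0.0320 capped, and for cisplatin 0.0729 across boundaries, -0.0093 without TGG (opposite sign) and 0.317 capped. The correlation of the comparisons was 0.470 with at least 100 reads in all 8 libraries and 0.241 without ribosomal protein genes. With placed coding reads TEL1 stood at -0.087, SAE2 at -0.27, MET30 at -0.22, SMF3 at -0.23 and HEL2 at -0.038, and from codon 51 TEL1 at -0.37, SAE2 at -0.36, SKI8 at -0.016, MET30 at -0.24, SMF3 at -0.64, CTS1 at 0.19 and HEL2 at -0.12, all opposite in sign. Without GA/AG replicate 2 SAG1 (-0.027, against 0.43 at most), HEL2 (-0.057, against 0.20) and P-site GGG (-0.018, against 0.21) changed sign, as did SAG1 without cisplatin replicate 1 (-0.19, against 0.79). At 500 reads A-site CGA (-0.24) and CTC (-0.15), P-site GGG (-0.083) and E-site CTT (-0.015) of GA/AG and P-site CTC (-0.025) and TCA (-0.050) of cisplatin changed sign, and with frame 0 reads A-site CTC (-0.13) and P-site GGG (-0.0022) of GA/AG and E-site TCG (0.020) of cisplatin. Where no cause is given here, the cause was not tested. Depth limits codon positions and UTR windows, where 20 reads over 4 libraries suffice for a test.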

Other observations

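All tests in this part were chosen only after the result they concern was seen, and so were the genes named in this paragraph. With cisplatin TRP2 rose by 0.63 ± 0.07, TRP3 by 0.77 ± 0.06, TRP4 by 0.45 ± 0.10 and TRP5 by 0.71 ± 0.05 on the log2 scale (n = 2 libraries per group, edgeR), each an enzyme of tryptophan synthesis, which was not tested as a list. The list of Gcn4 targets and amino acid biosynthesis also rose (35 of 52 up, 9 down, median 0.39), so these rises need not be particular to tryptophan. TRP1, mutated in W303, had 2.34 and 0.82 CPM in DMSO and 2.11 and 2.62 in cisplatin. The permeases TAT1 (-0.98 ± 0.13) and TAT2 (-0.28 ± 0.10), which import tryptophan, fell, and the tryptophan tRNA synthetase WRS1 stood at -0.16 ± 0.07 (adjusted p = 0.0816). The 4 ribonucleotide reductase genes, not tested as a list, stood at 0.35 ± 0.06 (RNR1), 0.52 ± 0.06 (RNR2), 2.76 ± 0.32 (RNR3) and 0.59 ± 0.06 (RNR4), each past the threshold. FRE1, a metal reductase (2.13 ± 0.08), and CTR1, a copper importer (0.89 ± 0.06), rose.

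In the purified libraries TEL1, TOM71, ROD1 and SEG2 together held 2.18% and 1.961% of gene reads in WT and 5.96% and 7.86% in GA/AG, against 0.317% and 0.411% in DMSO and 1.62% and 0.219% in cisplatin. Cytosolic ribosomal protein genes held 15.9% and 16.1% in WT, 7.35% and 7.04% in GA/AG, 20.0% and 20.4% in DMSO, and 12.2% and 11.9% in cisplatin.

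Cytosolic ribosomal protein genes and other short reading frames were lower on GA/AG ribosomes. Fewer reads at start and stop codons weigh more in short genes, but on body reads from codon 51 the ribosomal protein median was -1.213, with 98.1% of 106 genes below 0, and other genes under 120 codons lay -0.9036 from those over 300 codons, both of which argue against it. Coding length alone is argued against for ribosomal protein genes by a median difference of -0.8423 from the 20 other genes closest in length, with 98.2% of 112 differences below 0. A length trend is still present among other genes (Spearman 0.359, and 0.247 on body reads) and is stronger within ribosomal protein genes (0.780, and 0.793 on body reads), so length stays open as part of the pattern. An effect of the 18S substitutions on which mRNAs are translated may remain as a hypothesis, and it was not tested. Different levels of these mRNAs in the cells could give the same pattern, and mRNA was not measured.

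Mitochondrially encoded genes held a share 3.306 times as large in WT as in GA/AG purified libraries. Cytosolic ribosomes carrying tagged 18S rRNA do not translate these mRNAs, so carry-over of mitochondrial ribosomes that differed between purifications could give this value, and it cannot be told apart from a change in the cells because each group has its own purifications. For less carry-over of membrane-bound ribosomes of every kind, nuclear genes with a hydrophobic segment were compared with length-matched genes. Their median difference was -0.04715 (quartiles -0.366 to 0.246, 1628 genes). Tagged cytosolic ribosomes also give reads of these nuclear genes and can hide a change in carry-over, so this value cannot decide it. An effect of the substitutions on mitochondria stays open and was not tested.

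Tryptophan codons held more reads in the A site with cisplatin. If cisplatin on neighbouring guanines of the mRNA held ribosomes with GG in the A-site codon, other GG codons would rise too. Those other than TGG changed by -0.0093, which argues against that case alone. GG across codon boundaries, whose A-site difference is given above, and GG further from the A site were measured. No outcome was set for them to be weighed against, so the account stays open there. Footprint ends shifted in cisplatin replicate 2, whose P-site value stood apart, are argued against by a TGG change of 0.8623 without that library. Occupancy 10 codons upstream of TGG rose by 0.679 in the mean, against -0.263 to 0.0857 at 3 to 8 and 13 to 18 codons, which would be seen if ribosomes stayed longer at tryptophan codons and others queued behind, a hypothesis found and tested on the same data. A shortage of charged tryptophan tRNA may underlie a longer stay, and neither tRNA nor tryptophan was measured here.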
